A study of Mus musculus with 6 samples.

How the data were processed

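Values were deposited for 6 arrays, 1 per fibroblast line, and no other column was present in the table. Per the labels' protocols, the fibroblasts were grown for the same number of passages, RNA was purified with column kits, amplified and labelled with biotin, and hybridised to Affymetrix mouse arrays. Per the submitters' processing notes, the authors used R 2.15.3 and GCRMA 2.28.0. GCRMA corrects the background, normalizes arrays to a common distribution and summarizes probe sets on a log scale, so differences between arrays in overall brightness are removed before any comparison. The deposited values are log2 values, from 0.922 to 14.393, and were used without a further transformation. Scanner intensities were not analysed here.

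Probe sets were named through the platform annotation. Of 22626 probe sets 20380 had 1 gene symbol, 691 had several and 1555 were not listed; the last 2 kinds were left out of the gene tests. For 20351 of those with 1 symbol the Entrez identifier was found in a RefSeq gene table of the assembly GRCm38.p6, and 0 symbols changed. Gene order along chromosomes was taken from that table, and no coordinates are given because the build behind the array annotation was not given in the sources used here. Of 12393 genes, 4956 had more than 1 probe set, and each gene was represented by the probe set with the highest mean over the 6 arrays. Genes with a log2 value of at least 4 on at least 3 arrays were kept, which left 8382.

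Lines were grouped by the chromosome stability and the genotype in the labels. The unstable minus stable difference was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), without a block. The BubR1 contrast and the difference between the BubR1 and CDC20 effects came from a model with 4 groups. With 3 lines against 3 an exact permutation test cannot go below 0.1, and with 3 pairs a sign-flip test cannot go below 0.25, so neither was used. Gene lists, 31 in all, were written before the data were examined, as were the tests, the alternatives and the rule for named genes. Those with at least 5 tested members, 29 lists, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry; the endothelial list, with 4 members, and the list of Y-linked genes and X inactivation, with 3, were not tested. Where a count is given as adjusted over the list alone, only the list's members entered the adjustment. Of 10 genes that occur in 2 lists, Cd68 is both a macrophage and a lysosome gene and Cdkn1a both a p53 target and a senescence gene, and fibroblasts also express some markers of other cell types.

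The rule named Bub1b and Cdc20; up to 15 genes in each direction past the threshold, the places left being filled by the smallest unadjusted p among genes with an absolute log2 difference of at least 1 and the same sign in all 3 pairs (39 genes higher and 12 lower met this); up to 4 members of each list by p; the 10 smallest p for BubR1; and the 5 highest and 5 lowest differences of the CDC20 pair among genes with a mean log2 level of at least 6.

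Same-numbered lines deviated together from their group means. Correlations of the deviations across genes were 0.812, 0.681 and 0.602 for pairs 9515, 9938 and 10074. For lines of different numbers in the other group they were -0.673 to 0.153. Deviations within a group sum to 0, so positive same-number values push the others below 0. Without this centring, same-numbered lines correlated at 0.998, 0.996 and 0.995 over all probe sets, and other lines at 0.989 to 0.994. The numbers, which come from the sample titles, were therefore taken to pair the lines, and the fit with the pair number as a block is given where it changes a call or a count. Standard errors of gene differences come from fits without the block, so they include differences between pairs. For the BubR1 contrast and the difference between effects that fit had a separate effect for each locus, and its list tests were added after seeing the data. Alternatives were other filters on low values, the mean of a gene's probe sets, renormalization, an intensity trend with a robust prior, array weights, other set tests, other controls and leaving out each line or pair.

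The tests were tested on simulated data for the unstable against stable comparison, with the real means, pair effects and spread of 8382 genes and 200 genes changed by known folds, in 20 simulations. Without the block, 9.4% of genes changed 1.5-fold, 49.2% of those changed 2-fold, 84.6% of those changed 4-fold and 94.2% of those changed 8-fold were recovered, with a mean of 0.15 false calls. With the block the shares were 34.1%, 65.6%, 89.2% and 96.3%, with 4.1 false calls. A list lowered by 0.5 was called in 20 of 20 simulations by camera with the preset correlation and in 20 with an estimated one. Apart from the pair effects, members of that lowered list varied independently, and list calls used an unadjusted p under 0.05. The real replication list had an estimated correlation of 0.57 without and 0.34 with the block. The simulations therefore do not give the power of the estimated-correlation test for the real lists. A list with no true difference whose members shared 1 random shift per array was called in 13 of 20 with the preset correlation and in 1 of 20 with an estimated one. Figures were drawn with matplotlib 3.10.9.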

Results

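Transcript levels were measured on 6 Affymetrix arrays, each with 22626 probe sets and each hybridised with RNA of 1 line of mouse embryo fibroblasts, which are primary fibroblasts grown from embryos. The 3 chromosomally unstable lines comprised 2 BubR1 H/H lines, which carry a hypomorphic allele of the spindle checkpoint kinase BubR1, and 1 CDC20 AAA/AAA line, which carries a mutated form of the mitotic activator CDC20. The 3 stable lines were wild type and comprised 2 BubR1 +/+ lines and 1 CDC20 +/+ line. The numbers 9515, 9938 and 10074 in the sample titles each belong to 1 unstable and 1 stable line, and these are called pairs here; pairs 9515 and 9938 hold the BubR1 lines and pair 10074 the CDC20 lines. Array medians lay between 6.156 and 6.197 on the log2 scale, and 64.2% to 64.7% of the probe sets reached a log2 value of at least 4. The number of arrays limits the precision of every value. The labels do not say whether the lines came from separate embryos, so p-values measure the spread between these lines.

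Bub1b, the gene of BubR1, was lower in each unstable line than in the stable line of the same number. It measured 6.15 against 7.81 in pair 9515, which is 3.17-fold lower, and 6.43 against 8.51 in pair 9938, which is 4.23-fold lower. In the CDC20 pair, in which the labels name no BubR1 mutation, it measured 7.00 against 7.61, which is 1.53-fold lower. That is -0.62 on the log2 scale, beside medians of -0.77 and -0.68 for the mitosis and kinetochore gene lists in the same pair. Over the groups, the level of Bub1b was 7.98 ± 0.47 (SD, n = 3) in stable and 6.52 ± 0.43 (SD, n = 3) in unstable lines. This difference of -1.45 (SE 0.31) on the log2 scale did not pass the limma test over all genes (adjusted p = 0.999). Bub1b had only 1 probe set that named it alone, so the sizes of its differences could not be checked against another. Cdc20 measured 10.94 ± 0.18 (SD, n = 3) in stable and 10.37 ± 0.36 (SD, n = 3) in unstable lines, with pair differences of -0.10, -0.81 and -0.81 for pairs 9515, 9938 and 10074, and did not pass the test (adjusted p = 0.999 by limma). The 3 probe sets of Cdc20 were all lower in the unstable line of each pair. As a check of embryo sex, Xist, the transcript of the inactive X chromosome, lay at 10.38 and 10.73 in the unstable and stable lines of pair 9938 by its first probe set and at 1.65 to 1.86 in the other 4 lines. The Y-linked Eif2s3y was at 2.07 and 2.20 in pair 9938 and at 11.25 to 11.71 in the other lines. Both lines of pair 9938 thus had a female pattern, and the lines of pairs 9515 and 10074 a male one. The lines of each pair matched in sex, but the BubR1 pairs differed, so sex is part of the difference between pairs.

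**Figure D1:**
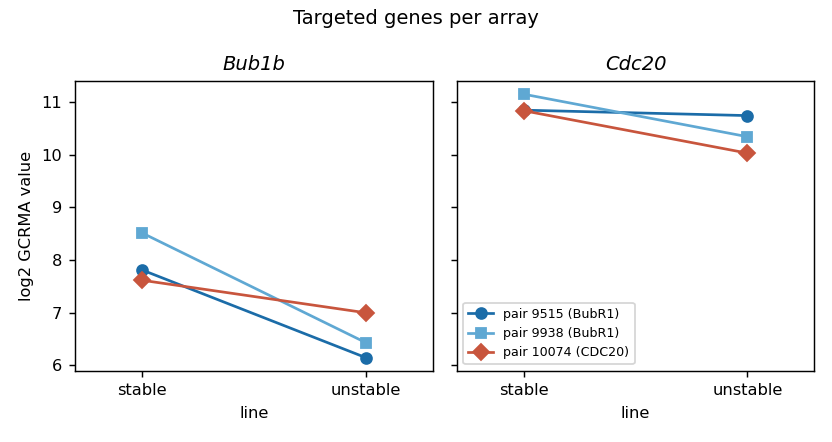
Log2 GCRMA value of Bub1b and of Cdc20 (brightest probe set) on each of the 6 arrays, with a line joining the stable and the unstable line of each pair; each point is 1 array. Bub1b lies lower in the unstable line of every pair, by 1.53-fold to 4.23-fold.

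The main comparison asked which transcripts differ between the 3 unstable and the 3 stable lines. No single gene passed, so the genes that follow are given as values that did not pass the test. Agtr2, an angiotensin II receptor, was 2.99-fold higher in unstable lines, with pair differences of 1.48, 1.86 and 1.41 on the log2 scale. Ifit1, an interferon-induced gene, was 6.61-fold higher, and its pair differences were 1.60, 2.16 and 4.42. Mmp10 and Mmp13, which encode secreted matrix metalloproteinases, differed by 2.20 (SE 0.81) and 1.68 (SE 0.56), and the chemokine genes Cxcl10 and Ccl8 by 1.61 (SE 0.44) and 1.34 (SE 0.48). The imprinted gene Nnat had the smallest unadjusted p among genes at least 2-fold higher, being 2.47-fold higher (SE 0.24 on the log2 scale). The other genes named by the rule for higher values were Sytl2 at 1.34, Crmp1 at 1.17, Gabrb1 at 1.09, Nap1l2 at 1.23, the smooth muscle myosin gene Myh11 at 1.16, the granzyme gene Gzme at 1.39, the interferon-inducible GTPase gene Irgm1 at 1.14 and Rgs5 at 1.14. In the other direction, only 12 genes met the rule: Bub1b; the water channel gene Aqp1 at -1.78 (SE 0.84); U90926 at -2.16 (SE 1.07); Nrarp, a regulator of Notch signalling, at -1.06 (SE 0.37); Ilkap at -1.20; Car6 at -1.14; Fgl2 at -1.02; the desmosomal gene Pkp1 at -1.13; Scara5 at -1.05; Cdsn at -1.10; Coch at -1.25; and the prostaglandin-degrading enzyme gene Hpgd at -1.05. Nap1l2 and Rgs5 in 1 stable line each, and U90926, Car6 and Scara5 in 1 unstable line each, lay below the log2 floor of 4, so their sizes are approximate. Nnat lay just above that floor in the stable lines of pairs 9515, 9938 and 10074, at 4.235, 4.199 and 4.097, so its size is approximate too.

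Of 8382 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 359 genes, of which 113 were higher and 246 lower, where 419 are expected by chance. With the pair number as a block the counts past the adjusted threshold were again 0 and 0, the smallest adjusted p was 0.262, and 1019 genes had an unadjusted p under 0.05, of which 439 were higher and 580 lower.

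Genes of the cell division cycle were lower in unstable lines. Of the DNA replication and G1/S list, 39 of 39 measured members were lower, with a median difference of -0.49 on the log2 scale and pair medians of -0.27, -0.62 and -0.57 in pairs 9515, 9938 and 10074. Of the mitosis and G2/M list, 41 of 42 were lower, with a median of -0.57 and pair medians of -0.23, -0.67 and -0.77. Of the kinetochore and spindle checkpoint list, which leaves out Bub1b and Cdc20, 23 of 23 were lower, with a median of -0.53 and pair medians of -0.19, -0.65 and -0.68. These counts are over group means. Lower in all 3 pairs were 37 of the 39, 36 of the 42 and 20 of the 23 members. Among the members, the replicative polymerase gene Pole differed by -0.74 (SE 0.16), the replication factor Mcm10 by -0.76 (SE 0.17) and the cyclin E gene Ccne1 by -0.62 (SE 0.15). The condensin gene Ncapd2 differed by -0.68 (SE 0.15), the mitotic kinesin Kif20a by -0.67 (SE 0.17), the G2/M transcription factor Foxm1 by -0.74 (SE 0.20) and the centromere protein gene Cenpk by -0.73 (SE 0.16).

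These 3 lists fell against all other genes in limma's camera with a preset correlation of 0.01, at adjusted p = 2.3e-24, 6.6e-19 and 2.9e-11. None of these calls held with an estimated correlation, at adjusted p = 0.344, 0.473 and 0.473 with an estimated correlation. Of single members, 0 of each list passed the limma test adjusted over the list alone or over all genes. With the pair number as a block, 29 of the 39 replication, 36 of the 42 mitosis and 14 of the 23 kinetochore members fell when adjusted over the list alone, and 0 over all genes. Those blocked counts changed with the pair left out. Without pair 9515 they were 29, 38 and 16, without pair 9938 they were 14, 0 and 5, and without pair 10074 they were 8, 0 and 1. The list medians without pair 10074 were -0.48, -0.42 and -0.44, so the counts fell more than the medians did. With 1 line left out the calls stayed, but the mitosis median shrank to -0.29 without the unstable line of pair 10074 and to -0.37 without the stable line of pair 9938, and the kinetochore median to -0.31 without either. Macrophage and leukocyte markers, measured beside them, had pair medians of -0.24, 0.18 and -1.20.

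**Figure D2:**
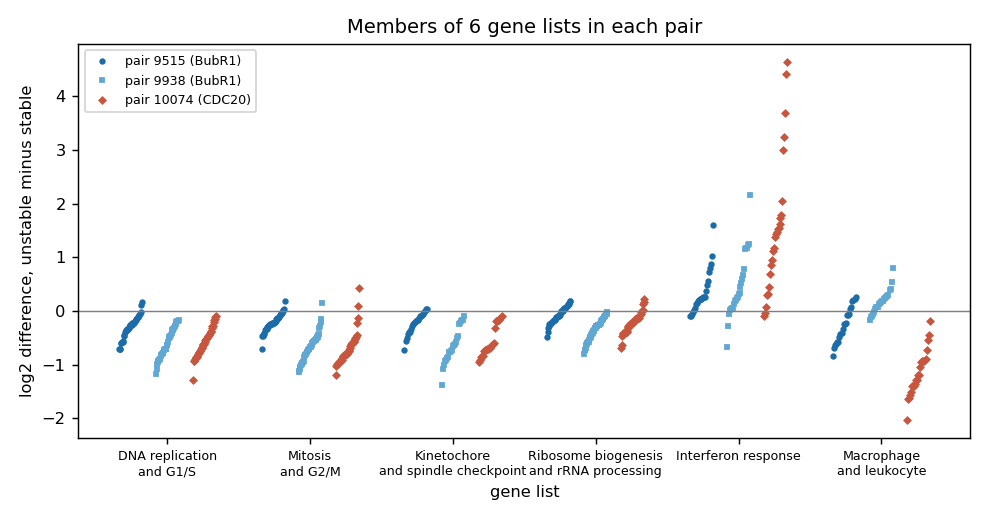
Log2 difference, unstable minus stable, of each measured member of 6 gene lists, ordered by size within each of the 3 pairs; each point is 1 gene. The replication, mitosis and kinetochore members lie mostly below 0 in each pair, and the interferon members reach highest in the CDC20 pair, where the macrophage and leukocyte members lie below 0.

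Genes of biosynthesis were lower by smaller amounts. Of the ribosome biogenesis and rRNA processing list, 50 of 50 members were lower, with a median of -0.21 and examples Polr1a, the large subunit of RNA polymerase I, at -0.50 (SE 0.12) and Bysl at -0.36 (SE 0.10). Of the nucleotide and one-carbon synthesis list, 21 of 23 were lower, with a median of -0.17, among them Umps at -0.40 (SE 0.12) and Phgdh, the first enzyme of serine synthesis, at -0.37 (SE 0.12). Of the cholesterol and fatty acid synthesis list, 23 of 27 were lower, with a median of -0.14, among them Fasn, the fatty acid synthase, at -0.28 (SE 0.13) and Sqle at -0.24 (SE 0.12). In pairs 9515, 9938 and 10074 the medians were -0.089, -0.30 and -0.21 for ribosome biogenesis, -0.088, -0.29 and -0.17 for nucleotide synthesis and -0.037, -0.13 and -0.25 for cholesterol synthesis. The lists fell by camera with the preset correlation at adjusted p = 3.4e-14, 1.6e-06 and 0.0019, against adjusted p = 0.345, 0.344 and 0.601 with an estimated correlation. In all 3 lists 0 members passed adjusted over the list alone, with or without the block. The counts of lower members are over group means. Lower in all 3 pairs were 27 of the 50 ribosome biogenesis, 14 of the 23 nucleotide and 14 of the 27 cholesterol members. The ribosome biogenesis median shrank to -0.13 without the stable line of pair 9938. The cholesterol list no longer passed without the stable line of pair 9938, where its median was -0.09, or without the unstable line of pair 9515, where it was also -0.09.

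Interferon-response genes were higher in unstable lines, by far the most in the CDC20 pair. Of 25 measured members 24 were higher over the group means and 16 in all 3 pairs. The median was 0.64, with pair medians of 0.23, 0.32 and 1.45 in pairs 9515, 9938 and 10074. Examples are the guanylate-binding protein gene Gbp2 at 0.84 (SE 0.34) and the transcription factor gene Irf9 at 0.96 (SE 0.40). Gbp3 lay below the log2 floor of 4 in all 3 stable lines and at 4.02, 4.38 and 6.82 in the unstable lines of pairs 9515, 9938 and 10074. The list rose by camera with the preset correlation at adjusted p = 1.3e-07, against adjusted p = 0.593 with an estimated correlation. Of its members 0 passed adjusted over the list alone, and 9 did with the pair number as a block; with the block, the count was 4 without pair 9515, 5 without pair 9938 and 6 without pair 10074. The list median was 0.14 without the unstable line of pair 10074 and 1.02 without that of pair 9515, and the call stayed. Without the block and without pair 10074, 3 passed adjusted over the list alone. In pair 10074 the macrophage and leukocyte markers were lower, with a median of -1.20.

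A further 6 lists rose by camera with the preset correlation. Of the senescence and secretome list, 20 of 27 members were higher, with a median of 0.30, among them Mmp10, Mmp13 and Ccl8, and the inflammatory cytokine gene Il6 at 0.74 (SE 0.33). Of the p53 targets 19 of 26 were higher, with a median of 0.13; examples are the pro-apoptotic gene Pmaip1 at 0.67 (SE 0.28) and Plk2 at 0.25 (SE 0.10). Of the Hox and axial position genes 21 of 28 were higher, with a median of 0.28, among them Hoxa10 at 0.41 (SE 0.18) and Hoxb9 at 0.52 (SE 0.32). Of the lysosome and autophagy genes 38 of 51 were higher, with a median of 0.10, of the hypoxia targets 12 of 18, with a median of 0.10, and of the imprinted and growth genes 10 of 12, with a median of 0.08, among them Mest at 0.78 (SE 0.45). In pairs 9515, 9938 and 10074 the medians were 0.20, 0.34 and 0.067 for senescence, 0.013, 0.16 and 0.15 for p53, 0.11, 0.27 and 0.12 for Hox, 0.076, 0.19 and 0.027 for lysosome, 0.18, 0.052 and 0.0045 for hypoxia and 0.080, 0.14 and 0.086 for imprinted genes, so that p53 in pair 9515 and senescence, lysosome and hypoxia in pair 10074 were near 0. Pmaip1 was at -0.026 in pair 9515 and Il6 at -0.19 in pair 9938. The counts of higher members are over group means. Higher in all 3 pairs were 15 of the 27 senescence, 11 of the 26 p53 and 13 of the 28 Hox members. For lysosome, hypoxia and imprinted genes they were 16 of 51, 7 of 18 and 5 of 12. The camera tests gave adjusted p = 0.0034 for senescence, 0.0014 for p53, 0.0048 for Hox, 8.7e-04 for lysosome, 0.017 for hypoxia and 0.044 for imprinted genes. In the same order they gave adjusted p = 0.344, 0.344, 0.516, 0.601, 0.344 and 0.593 with an estimated correlation. No member passed adjusted over the list alone, and with the block only the senescence members Mmp10, Ccl8 and Mmp12 did, Mmp12 with 1 stable line below the log2 floor of 4. The senescence median shrank to 0.11 without the stable line of pair 9515 (adjusted p = 0.044 by camera) and the p53 median to 0.077 without the stable line of pair 9938 (adjusted p = 0.018 by camera). The lysosome, hypoxia, Hox and imprinted calls were lost when single lines were left out, with median differences of 0.02 for lysosome, 0.06 for hypoxia, 0.13 for Hox and 0.06 for imprinted genes in such a fit. Other fits that left out lines gave these lists medians above those with all lines, with ranges given below.

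**Figure D3:**
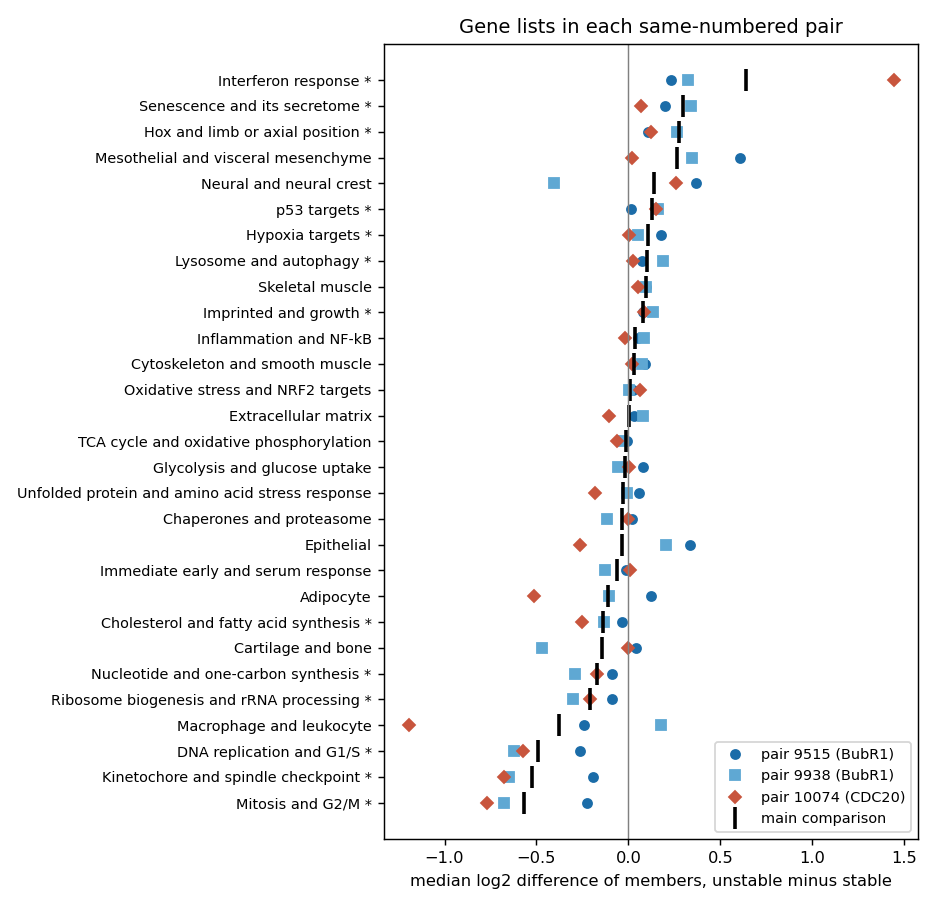
Median log2 difference, unstable minus stable, of the members of each of the 29 tested gene lists in each pair (points) and in the main comparison (black bars), with an asterisk where camera with the preset correlation passed. The 3 cell division lists have medians of -0.57 to -0.49 and the interferon list 0.64; no list passed with an estimated correlation.

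The other 16 tested lists did not pass. Those of metabolism, protein quality and signalling had medians near 0: inflammation and NF-kB 0.04, extracellular matrix 0.002, glycolysis -0.02, the TCA cycle and oxidative phosphorylation -0.01, chaperones and proteasome -0.03, the unfolded protein response -0.03, NRF2 targets 0.01 and immediate early genes -0.06. Of the markers of other cell types, those of smooth muscle had a median of 0.03, skeletal muscle 0.09, cartilage and bone -0.14, adipocytes -0.11, epithelium -0.03, neural crest 0.14 and mesothelium 0.27. The smooth muscle, cartilage, epithelial and mesothelial medians changed sign in fits that left out lines, with ranges given below. Over the group means all 22 macrophage and leukocyte markers were lower, with a median of -0.38, but in pair 9938 only 5 of the 22 were, and the result turned on single lines. The median was 0.36 without the unstable line of pair 9515 and 0.02 without the stable line of pair 9938, whereas the list passed by camera at -1.26 without the stable line of pair 9515 (adjusted p = 4.3e-06) and at -1.12 without the unstable line of pair 9938 (adjusted p = 1.4e-05). Examples are Laptm5 at -0.67 (SE 0.92) and Csf1r, the receptor of the macrophage growth factor, at -0.55 (SE 0.71). That list did not pass (adjusted p = 0.278 by camera with the preset correlation); with the pair number as a block it fell, at adjusted p = 4.0e-04 by camera and adjusted p = 0.656 with an estimated correlation. The smooth muscle list (adjusted p = 0.074) passed by camera without the filter (0.035), with the stricter filter (0.043) and with the mean of probe sets (0.013). With the pair number as a block, and only then, some members passed adjusted over the list alone by limma: Cxcl10 and Ccl5 of inflammation (adjusted p = 0.049 each), Aldh3a1, Gsta3 and Gpx3 of NRF2 targets (0.023 each), Col10a1 and Acan of cartilage and bone (0.035 and 0.046), Pkp1 and Krt7 of epithelium (0.032 and 0.040) and Pparg of adipocytes (0.0046). Ccl5 lay below the log2 floor of 4 in all stable lines, and Aldh3a1, Gsta3, Acan and Krt7 in some lines. The test's direction was up for glycolysis and epithelial genes although their medians were below 0, up for extracellular matrix although its mean was -0.004, and up for skeletal muscle although its mean was -0.03.

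Within the BubR1 lines, the comparison of 2 H/H with 2 wild-type lines asked what accompanies the hypomorphic allele alone. The imprinted gene Nnat was 0.99 higher on the log2 scale (SE 0.10), Agtr2 1.67 higher (SE 0.18) and Ifit1 1.88 higher (SE 0.25). The interferon-induced protease gene Usp18 lay below the log2 floor of 4 in both wild-type lines and at 4.82 and 5.18 in the H/H lines. Catsper2, a sperm ion channel gene, was 1.00 higher, the amine oxidase gene Aoc3 1.17, the mesothelial transcription factor gene Wt1 1.07 and the peptide hormone gene Cck 0.92. In the wild-type lines of pairs 9515 and 9938, Catsper2 lay at 4.003 and 4.075 and Nnat at 4.235 and 4.199. These levels are just above the floor, so the sizes for both genes are approximate. Ivd, which encodes isovaleryl-CoA dehydrogenase and lies 3 tested genes from Bub1b, differed by -1.75 (SE 0.20), and Cenpk by -0.74 (SE 0.11). For Ivd a second probe set differed by -0.32, so that its size depends on the probe set.

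These 10 genes are those of smallest p and did not pass: of 8382 genes 0 were higher and 0 lower at an adjusted p under 0.05 by limma, with 264 at an unadjusted p under 0.05 where 419 are expected. Of the gene lists, 15 of 29 passed by camera with the preset correlation, 10 higher and 5 lower, and 0 with an estimated correlation, where those 15 had an adjusted p of 0.486 to 0.651 with an estimated correlation. The 5 that fell were replication with a median of -0.48, mitosis with -0.42, kinetochore with -0.44, ribosome biogenesis with -0.21 and nucleotide synthesis with -0.18. The 10 that rose were senescence with 0.34, interferon with 0.26, Hox with 0.24, mesothelium with 0.23, hypoxia with 0.15, p53 with 0.15, lysosome with 0.13, smooth muscle with 0.12, inflammation with 0.08 and extracellular matrix with 0.04. Adjusted over the list alone by limma, 3 interferon members and 1 mesothelial member passed. With the pair number as a block, 0 genes passed, 719 had an unadjusted p under 0.05, and 17 lists passed by camera and 0 with an estimated correlation: extracellular matrix no longer passed (adjusted p = 0.062), while cholesterol (0.015), epithelial (0.020) and imprinted genes (0.037) did.

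In the CDC20 pair, Ifit1 lay at 10.66 in the AAA/AAA line and 6.24 in the wild-type line, the largest difference among genes with a mean level of at least 6. Usp18, below that mean level, was 4.645 higher, at 9.49 in the AAA/AAA line against 4.85 in the wild-type line. The interferon-induced genes Irgm2 and Ifit3 were 2.19 and 2.05 higher, Gbp7 1.97 higher and Gzme 2.1 higher. At the other end were Cdsn at -2.66, Fcrls, a gene of macrophages and microglia, at -2.44, Coch at -2.27, the stem cell marker gene Lgr5 at -2.08 and Hpgd at -2.06. In this pair 77 genes were at least 2-fold higher and 143 at least 2-fold lower, against 28 and 15 in pair 9515 and 116 and 69 in pair 9938. With 1 line per genotype there is no replicate check, and no p is given for this pair alone. Against 10000 random lists of the same size and level, the interferon median of 1.45 lay at percentile 100 and those of p53, Hox and neural crest genes at 99.97, 99.79 and 99.39. The replication, mitosis, kinetochore, ribosome biogenesis, macrophage, cholesterol and unfolded protein response medians lay at percentile 0 and those of extracellular matrix, adipocyte, nucleotide and TCA cycle genes at 0.080, 0.17, 0.185 and 1.16. Members of a list are correlated and random genes are not, so these percentiles are more extreme than the evidence and are no test.

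The 3 pairs, which share no line, were compared gene by gene. Agtr2, Gbp3, Ifit1 and Ms4a4d were at least 2-fold higher in the unstable line of all 3 pairs, and U90926 at least 2-fold lower. Of these, Gbp3 lay below the log2 floor of 4 in all stable lines. Ms4a4d did so in the stable line of pair 9515 and U90926 in the unstable line of pair 9938. Only Agtr2 and Ifit1 were thus compared above the floor throughout. Agtr2, Gbp3, Ifit1 and U90926 were also named by the rule, whereas Ms4a4d was named after its values were seen. None of these 5 passed the limma test. For the 3 other combinations of signs the mean count was 0. At 1.5-fold there were 40 genes, 23 higher and 17 lower, against a mean of 2.67 for the other combinations and a highest of 6. Of the 17 lower genes 4 belonged to the 3 cell division lists, where 0.21 are expected from the lists' share of tested genes. The correlation across genes of the pairs' differences was 0.28 for pairs 9515 and 9938, 0.28 for 9515 and 10074 and 0.34 for 9938 and 10074; genes are not independent replicates, and no p is given. The median lay on the same side of 0 in all 3 pairs for 18 of the 29 lists.

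The test of the difference between the BubR1 and the CDC20 effect assumes that the lone CDC20 lines vary like the BubR1 lines. Ifit1 differed between the effects by -2.54 (SE 0.44) on the log2 scale, with the larger rise in values in the CDC20 pair, and did not pass (adjusted p = 1.00 by limma). Usp18 differed by -3.58 (SE 0.28), with both BubR1 +/+ lines below the log2 floor of 4, and did not pass either. Over all genes 0 passed an adjusted p under 0.05 by limma, and 133 had an unadjusted p under 0.05 where 419 are expected; with the pair number as a block 0 passed and 476 had an unadjusted p under 0.05. The largest difference between effects for a targeted gene was for Bub1b, with -1.87 in the BubR1 lines and -0.62 in the CDC20 pair.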

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

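The gene and list counts of the real split were planned; the camera tests of the difference between effects, the tests on gene order, probe sets, level-matched lists, leukocyte markers, bright interferon genes and stable lines, and the other splits were chosen after results they bear on had been seen. The effect in the BubR1 lines and that in the CDC20 pair differed for 4 gene lists in camera with the preset correlation on the difference itself, and for 0 with an estimated correlation, at adjusted p = 0.898 each. With the pair number as a block 6 lists differed, the 4 and also macrophage markers (median difference 1.09, adjusted p = 2.1e-19) and neural crest markers (-0.41, adjusted p = 0.019), and 0 with an estimated correlation. The median of the members' differences, BubR1 effect minus CDC20 effect, was -0.92 for interferon genes (medians 0.26 and 1.45, adjusted p = 1.8e-16 by camera). It was 0.26 for mitosis genes (-0.42 and -0.77, adjusted p = 9.3e-04), 0.14 for extracellular matrix genes (0.04 and -0.11, adjusted p = 0.0019) and 0.24 for the unfolded protein response (0.02 and -0.18, adjusted p = 3.3e-05). No group had 4 or more lines, so no line was tested as standing apart from its group.

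Genes beside Bub1b differed between BubR1 H/H and BubR1 +/+ lines. Over the 50 tested neighbours, 25 on each side, the mean absolute difference was 0.25 on the log2 scale, and 1.98% of 7366 windows of gene order had one as large; the same window in the CDC20 pair was reached by 33.3%, and without Ivd the share was 6.90%, so that gene carries much of the excess. Probe sets of 1 gene disagreed more among 21 neighbours with several bright probe sets than in any of 10000 random gene sets, a share of 0%, with a mean range of 0.38 against 0.15 in the random sets and a share of 55.5% in the CDC20 pair; without the 3 most discordant, Ivd (-1.75 and -0.32), Rpap1 and Nusap1, it was 2.5%. A candidate explanation is a stretch of chromosome inherited together with the H allele that differs in sequence under some probes. An effect of the allele on its neighbours stays open and untested. Bub1b itself had only 1 probe set, so whether such a sequence difference adds to its own lower values could not be checked.

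The DNA replication, mitosis and kinetochore lists were lower in the unstable lines. Random lists matched on mean level reached medians no lower than -0.22, and 0% of 10000 were as low as any of the 3 lists, which argues against a normalization error that depends on intensity. A larger leukocyte share in the unstable cultures is argued against in pairs 9515 and 10074, where the leukocyte marker medians were -0.24 and -1.20. Pair 9938, at 0.18, does not argue against such a share. The medians lay more than 2 standard errors below 0 in 2 of the 3 pairs and more than 2 above it in pair 9938. These standard errors are taken over 22 correlated markers of 1 pair and do not measure the spread between cultures. The biological difference the design names, chromosome instability, is only a hypothesis for the lower values. It was not tested against slower growth of these particular cultures for another reason.

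The 10 splits of the 6 lines are too few for a share under 0.05: the real split gave 0 genes and 13 lists past the threshold, and the highest of the other splits 48 genes and 15 lists. The 48 genes came from setting pair 9515 and the CDC20 AAA/AAA line against pair 9938 and the CDC20 +/+ line, which points to a structure of the samples beyond stability; exchanging the CDC20 lines gave 0 genes, so pairs alone do not give it. The macrophage marker means were 7.07, 7.31 and 8.72 on its first side and 9.84 to 10.03 on the other, and its cause was not tested. Among the 4 splits that part every pair, the real one gave 359 genes at an unadjusted p under 0.05 and 13 lists; the 3 others gave 54, 120 and 48 genes and 6, 10 and 3 lists. With the pair number as a block the real one gave 1019 genes and 14 lists, and the 3 others gave 191, 301 and 208 genes and 15, 11 and 3 lists.

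The interferon list was higher in CDC20 AAA/AAA than in CDC20 +/+. More leukocytes in the AAA/AAA culture are argued against by the macrophage and leukocyte markers, whose median there was -1.20, with Csf1r and Laptm5 at -1.20 and -1.40. Noise near the detection floor is argued against for the 16 members with a level of at least 6 in the CDC20 +/+ line, whose median difference was 1.31 (standard error 0.35), and stays open for the dimmer members; the first bound set for the list, a median of at least 1 by more than 2 standard errors among 15 members with a mean level of at least 6, was not met (1.18, standard error 0.37). The range of the list's mean level over the 3 stable lines, 0.81 against a difference of 1.58 in this pair, includes differences between pairs and so decides nothing. An effect of the CDC20 mutation cannot be told apart from variation between lines of 1 genotype because each genotype has 1 line.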

How the results depend on the processing

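Choices were changed singly, except that the block was also combined with a pair left out and with an estimated correlation; alternatives were written before the data were examined unless stated. With limma, 0 genes passed in either direction under every alternative, for unstable against stable lines, for BubR1 and for the difference between effects; genes at an unadjusted p under 0.05 numbered 144 (without pair 9938) to 1019 (replicate block). Of 1345 values of 80 named genes under alternatives, 1342 kept their direction and none passed; the 80 are those named for the main comparison and the leading members of called lists, and other named genes were not covered. For unstable against stable lines the replicate block changed the call of the macrophage list and no other list call. Lists past the threshold numbered 13 with all lines, 9 to 15 in fits that left out lines and 12 to 14 under the other single alternatives and 12 to 17 with the block and a pair left out, but 0 with an estimated correlation, 0 with fry and 0 with the block and an estimated correlation. Both combinations with the block, all list tests of the difference between effects, and the blocked list tests for BubR1 (17 lists against 15) and for the difference between effects (0 genes, 6 lists against 4), were chosen after seeing the data. With an estimated correlation, with or without the block, and under fry the medians stayed those of the camera test while the calls were lost: replication -0.49, mitosis -0.57, kinetochore -0.53, ribosome biogenesis -0.21, nucleotide -0.17, cholesterol -0.14, p53 0.13, senescence 0.30, interferon 0.64, lysosome 0.10, hypoxia 0.10, Hox 0.28 and imprinted 0.081. In fry the direction turned for glycolysis (median -0.020) and NRF2 targets (0.0063). The imprinted list lost its call with the stricter filter (0.060), with each array centred (0.087) and with array weights (0.056), and the smooth muscle list gained one without a filter (0.032), with the stricter filter (0.030) and with the mean of probe sets (0.068). Directions turned for epithelial genes without a filter (-0.034) and for NRF2 targets with the mean of probe sets (0.015) or array weights (-0.011), all uncalled. Leaving out each line or pair gave these lowest and highest medians for lists that lost, gained or turned: extracellular matrix -0.040 and 0.071, lysosome 0.017 and 0.17, glycolysis -0.042 and 0.016, cholesterol -0.25 and -0.088, chaperones -0.071 and 0.017, unfolded protein response -0.11 and 0.024, NRF2 -0.062 and 0.057, hypoxia 0.043 and 0.15, cartilage -0.60 and 0.24, macrophage -1.26 and 0.36, epithelial -0.27 and 0.53, mesothelial -0.22 and 0.47, Hox 0.10 and 0.39, imprinted 0.024 and 0.24, smooth muscle -0.019 and 0.12, inflammation -0.025 and 0.13, neural crest 0.0083 and 0.31. Csf1r ranged from -1.12 to 0.030, Laptm5 from -1.42 to 0.089 and Cd52 from -1.297 to 0.080, with the sign turned without the unstable line of pair 9515, which had low marker levels. The replication, mitosis, kinetochore, ribosome biogenesis, nucleotide, interferon, p53 and senescence lists kept their calls in every fit that left out lines, with medians of -0.57 to -0.35, -0.73 to -0.29, -0.69 to -0.31, -0.26 to -0.13, -0.21 to -0.13, 0.14 to 1.02, 0.077 to 0.16 and 0.11 to 0.39 in that order. Members past the threshold adjusted over the list alone, a count chosen after seeing the data, were 0 without the block; the replicate block gave 29 replication, 36 mitosis, 14 kinetochore and 9 interferon members, and the block without 1 pair 8 to 29, 0 to 38, 1 to 16 and 4 to 6. For kinetochore members these were 16, 5 and 1, for replication 29, 14 and 8 and for interferon 4, 5 and 6 without pairs 9515, 9938 and 10074. The stricter filter and the mean of probe sets gave 4 replication members each, and leaving out lines gave 0 to 3 interferon members. Agreement of 3 pairs was 40 genes at 1.5-fold against 5 at 2-fold. The share of windows as large as that of Bub1b was 3.08% with 10 genes on each side, 1.08% with 50, 6.90% without Ivd, 1.89% without cell division genes and 4.17% without both, all chosen after seeing the data. The share of random sets whose probe sets disagree as much as those of the Bub1b neighbours was 4.49% by the median range and 2.5% without the 3 most discordant neighbours. The cause was not tested where not stated. Signal over background limits the 12393 measured genes to 8382, and the sizes of differences near the floor are approximate.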

Other observations

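In this part the adipocyte list test was planned, and the tests of single adipocyte genes and of chromosome medians were chosen after values were seen. The mean level of the 22 macrophage and leukocyte markers was 7.07 and 7.31 in the unstable and stable lines of pair 9515, 10.03 and 9.84 in pair 9938, and 8.72 and 9.86 in pair 10074. Cartilage and bone markers were highest in pair 9515, at 6.57 and 6.52, against 4.75 to 5.17 in the other 4 lines. The adipocyte list did not pass (adjusted p = 0.436 by camera with the preset correlation): of 7 members 3 were lower in all pairs, and the median was 0.13 in pair 9515, -0.11 in pair 9938 and -0.51 in pair 10074. Its members of smallest p were Pparg and Cebpa. Pparg, the main transcription factor of fat cell formation, was lower in the unstable line of each pair, at -0.59, -0.79 and -0.63, and Cebpa at -0.32, -0.41 and -1.08; Pparg did not pass over the adipocyte list alone without the block (adjusted p = 0.474 by limma); only with the pair number as a block it fell when adjusted over that list alone (adjusted p = 0.0046 by limma) and did not pass over all genes (adjusted p = 0.262).

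No chromosome had a median near that of 1 extra copy in every cell, which is 0.58 on the log2 scale. Over the 19 autosomes and X, the median difference of a chromosome's genes reached at most 0.11 in absolute size, on chromosome 7 of the CDC20 pair at -0.11 (SE 0.017), followed by chromosome 4 of that pair at -0.094 (SE 0.019). Both lay further from 0 than those of any other chromosome, and their cause was not tested. Gains and losses that differ from cell to cell would cancel in such medians.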
